A study of Mus musculus with 1000 samples.

How the data were processed

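The series holds 1000 libraries of 3'-end RNA-seq from mouse brain. Per the labels' protocols, C57BL/6NCrl founder males were given ENU (N-ethyl-N-nitrosourea, a chemical that introduces point mutations), their mutations were bred to homozygosity, and brains without the cerebellum were taken from third-generation offspring. Per the labels' protocols, cDNA was made with the SMART-Seq v4 3' DE kit, which gives each sample of a plate row its own in-line index. The 12 samples of a row were then combined into 1 cDNA pool, each pool received its own combination of Nextera indices, and the 96 pools of 12 plates were sequenced together as 1152 libraries. Per the submitters' processing notes, the tools and builds include GSNAP, a read aligner, and the mouse build GRCm38; the version of the aligner, the counting tool and the annotation are not given in the sources used here.

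The only processed file used here was a lookup table, deposited as a spreadsheet. Per the file headers, it pairs a library name with the processed table that holds it. Its column of table names is text, and its 1 column of numbers was tested and is only a running row number. The table holds 0 columns of per-sample values. The expression values of these libraries are kept in a separate series, per the series' own design text, and were not analysed here. No gene could therefore be tested, no depth per library can be given, and the comparison of gene expression between ENU codes that had been planned was not run. The lists of microglial, astrocyte, interferon-stimulated, antigen-presentation, neuronal, oligodendrocyte, endothelial, blood, choroid plexus and cerebellar genes fixed for that comparison gave no result for the same reason. The reference annotation was not used.

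Each library was placed by its title, which carries an ENU code, an animal number, a well, a plate number and an S number. Libraries were grouped by the ENU code. The labels do not state that this code is the pedigree, and reading the "G3" after the code as the generation and the digits after it as the animal number is a reading of the titles. The plates were divided into 2 sets of 12, neuro2172 to neuro2183 and neuro2184 to neuro2195, which is the division under which the S number follows from plate and row. The rule for naming ENU codes was to name those whose number of libraries was not the most common one, and beyond 5 such codes to give counts, with the smallest and largest codes named. The 15 codes of 6 libraries are therefore given as a count, except for those that shared a plate row.

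Counts were made of libraries per ENU code, of plate rows that hold 1 or 2 ENU codes, of libraries that match a name in the lookup exactly, and of processed tables per plate set. The order of animals along a plate row was measured as Spearman's rho between animal number and well column within each ENU code with at least 6 libraries, averaged over codes. Its p is two-sided, from 100000 permutations of the animal numbers within codes, with a threshold of 0.05. The code of the test was checked on simulated data in the 91 codes' real wells, with fewer permutations per layout than in the main test. It returned a mean rho of 1.0 for wells filled in order, and 4.5% of 1000 random layouts fell under the threshold. Both outcomes follow from how the layouts were made, so they check the code only. The alternatives were each plate set alone, full plate rows or full codes alone, Pearson's r, a looser match of names, and a count of tables per plate. These choices were made after the titles had been read and counted. The titles are the data for all results except the lookup counts, so the order test was not chosen blind to the layout. The 2 counts over all lookup names and the share of rows with 1 code on the plates neuro2184 to neuro2195 were added later. So were the counts under Other observations. The summaries of animal numbers were not among the planned results either. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.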

Results

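The series is 1 part of a screen for abnormal inflammation states in the brains of mice carrying ENU-induced mutations. It comprised 1000 libraries of brain without the cerebellum, each from 1 animal, and 0 animals had more than 1 library. All libraries carried the same tissue label, and their labels named neither a control group nor affected animals. The expression values were not analysed here, so the measurements below describe how the cohort was laid out in the library plates and not any gene.

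The libraries fell under 92 ENU codes. A code held a median of 12 libraries (mean 10.87 ± 2.46, SD, n = 92 codes). Of the 92 codes, 75 held 12 libraries and 15 held 6 libraries. The remaining codes were ENU57189B6 with 9 libraries and ENU57188B6 with 1 library, the smallest of the series. Animal numbers ran from 1 to 31 across the cohort. In 74 of the 92 codes at least 1 animal had a number above 12, and the median of the highest number per code was 16.

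The first question the layout bears on is whether the animals of different codes were prepared side by side. They were spread over 21 plates, with between 6 and 96 libraries of the series on each. A plate held between 1 and 9 codes of the series. Plates neuro2189, neuro2191, neuro2192 and neuro2194 held 1 code each. The other plates held at least 2, so animals of different codes shared those plates. The plate set neuro2172 to neuro2183 held 775 libraries of 70 codes on 12 plates, and the set neuro2184 to neuro2195 held 225 libraries of 22 codes on 9 plates. The sets were drawn so that the S number of a library, which runs from 1 in each set, equals the running position of its plate row among the 96 rows of the set, and this held for all 1000 libraries by that choice. No code was split between the plate sets (0 of 92), between plates (0 of 92) or between rows of a plate (0 of 92).

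The second question is whether an ENU code can be told apart from the cDNA pool in which its libraries were made, since a plate row is 1 pool. Libraries of the series occupied 89 plate rows. In 86 of them (96.6%) all libraries of the series carried 1 ENU code, and 75 of these rows were filled with 12 libraries of that code. The other 3 rows held 2 codes with 6 libraries each. Row E of plate neuro2186 held ENU57005B6 and ENU57109B6, row E of plate neuro2195 held ENU57032B6 and ENU57161B6, and row H of plate neuro2182 held ENU57403B6 and ENU57328B6. Within this series, a contrast between codes was therefore also a contrast between pools for every pair of codes except these 3 pairs. In each of these 3 rows, 1 code filled well columns 1 to 6 and the other filled columns 7 to 12. Within those pairs, a contrast between codes was thus also a contrast between in-line indices. Animals of 1 code always shared 1 pool, so a contrast between them lay within a pool. Counting also the libraries outside the series that the lookup places in the same 89 rows, 12 rows held 2 codes and 77 held 1. These are complete counts of names, so no sampling error applies to them.

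**Figure D1:**
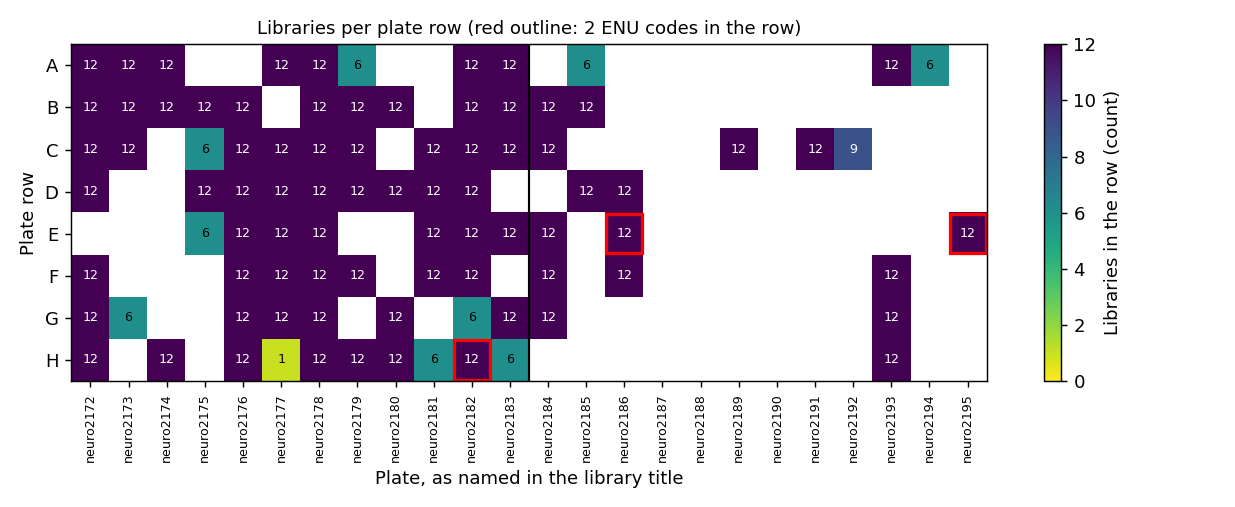
Number of libraries of the series (count, printed in each cell and shown by colour) in each plate row (A to H, vertical axis) of the plates neuro2172 to neuro2195 (horizontal axis), with a black line between the 2 plate sets. White cells are rows with no library of this series, and the 3 rows outlined in red are the rows with 2 ENU codes.

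The third question is whether the animals of a code were placed in the wells in a fixed order. The correlation of animal number with well column was above 0 in all 91 codes with at least 6 libraries. The mean Spearman's rho between animal number and well column was 0.94 ± 0.14 (SD, n = 91 codes). In a two-sided permutation test of the animal numbers within codes, p was 1e-05, the smallest that 100000 permutations can give, and the largest mean rho in either direction among the permutations was 0.15 in size. In 57 codes the order was complete, with a rho of 1. These include all 15 codes with 6 libraries and ENU57189B6 with 9, in which fewer wells had to be in order than in a full row. The lowest value was 0.16, in ENU57121B6, followed by 0.23 in ENU57445B6 and 0.43 in ENU57132B6. The mean was 0.94 within the 69 codes of plates neuro2172 to neuro2183 and 0.92 within the 22 codes of plates neuro2184 to neuro2195, each with p = 1e-05 by the same permutation test. Because each well column of a row received its own in-line index, the order of the animals was also the order of the index positions in those 57 codes.

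The last question is where the values of the libraries are kept and whether 1 table holds them all. The lookup named 23231 libraries in 3 processed tables of 7743, 7743 and 7745 libraries. All 1000 libraries of the series matched a name exactly, and all 1000 were assigned to the third table, of which they made up 12.9%. Both plate sets of the series were thus placed in 1 table.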

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

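The order of animals along the wells stayed past the threshold under each alternative run. The other results are counts or shares with no test. The median number of libraries per ENU code was 12 in either plate set. The share of plate rows with 1 ENU code was 96.2% among full rows and 98.6% on plates neuro2172 to neuro2183, against 96.6% over all rows. On plates neuro2184 to neuro2195, a setting added after seeing the data, it was 90%, with 2 of 20 rows holding 2 codes. That share rests on only 2 mixed rows, and the cause was not tested. The mean correlation of animal number with well column was 0.92 for codes with 12 libraries and 0.92 with Pearson's r. A looser match of names again found 1000 libraries, and no plate was divided between processed tables. With every name in the lookup counted, also chosen after seeing the data, the share of the same 89 rows with 1 code was 86.5%. Names added to a row can only lower this share or leave it unchanged. The drop from 96.6% arose because the added names in some rows carried a second code. Over all 192 plate rows of both plate sets in the lookup, also chosen later, the share was 90.6%. No paired analysis was possible, since 0 animals had more than 1 library and the labels named no control group. The alternatives planned for the gene tests (replicate block, normalization, filter on low values) were not run because expression values were not analysed here. The depth of the libraries is unknown.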

Other observations

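The counts in this part were chosen only after the lookup had been seen. They rest on library names alone and use no measured value. The lookup held 2304 names on the plates of both sets, 96 on each of 24 plates, and 1304 of these names lie outside the series. Over all of them, 174 of the 192 plate rows carried 1 ENU code and 18 carried 2, and none carried more. None of the 210 ENU codes on these plates appeared in more than 1 of these 192 plate rows (0 of 210). Other plates of the lookup were not searched for these codes.

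Each of the 15 codes with 6 libraries shared its row with a second code once all names were counted. Among the 89 rows used by the series, 12 then held 2 codes and 77 held 1. A comparison of codes within 1 cDNA pool could thus be made in more rows with the libraries outside the series than within it, since the share of the 89 rows with 1 code was then 86.5%. Each of those 15 codes filled only columns 1 to 6 or only columns 7 to 12. Such a comparison would thus also be one between in-line indices. ENU57188B6 and ENU57189B6, with 1 and 9 libraries in the series, each had 12 names in the lookup on the plates of both sets. On these plates, the 14 names of these codes outside the series were the whole difference between series and lookup for the 92 codes. Lookup names on other plates were not counted by code.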
